A study of Arabidopsis thaliana with 16 samples.

How the data were processed

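RNA from whole seedlings of Arabidopsis thaliana was hybridised, as biotin-labelled cRNA, to 16 Affymetrix arrays. Per the labels' protocols, seedlings grown at 22 °C were either kept there or placed in a water bath at 37 °C for 1 h. The 8 groups combine these conditions with 4 genotypes, and each group holds 2 arrays. WT is the Col-0 accession. The hsfa2 line carries a knockout of HSFA2 in Col-0. QK lacks HSFA1A, HSFA1B, HSFA1D and HSFA1E in a background that mixes Col-0 and Ws. A2QK is QK with HSFA2 expressed from the viral 35S promoter.

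The deposited values are on a log2 scale and were made by the authors with RMA (background correction, normalization between arrays and summary of the probes of a probe set), per the submitters' processing notes. The software version, the chip definition and whether the 16 arrays were normalized together are not given in the sources used here. RMA sets the arrays to a similar overall distribution, so a change shared by most transcripts would be reduced, and dim probe sets are compressed toward a common floor. The values ran from 1.58 to 13.4, and the array medians from 4.87 to 5.20. Replicates of a group correlated with r of 0.959 to 0.995 across probe sets. Arrays have no read depth; their number, 2 per group, limits the precision. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

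Of 22810 probe sets, 64 controls were left out and 22746 were tested. The probe annotation listed 13513 of these with a single gene and 503 with several genes, and did not list 8730, which stay unnamed here. Of the single-gene probe sets, 13436 were matched to RefSeq genes of the TAIR10.1 assembly and 77 were not, and 13355 distinct genes were named. No gene was named from a probe set with several genes. No probe set was listed for HSFA1A, HSFA1B, HSFA1D, HSFA1E or HSFA2, so the levels of the disrupted and the added genes, which would check the genotypes, are not analysed here.

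Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each of the 8 groups over all 16 arrays. This left 8 residual degrees of freedom, and eBayes added 3.37 prior degrees of freedom. The comparisons were the 4 heat responses, hsfa2 and QK against WT and A2QK against QK at each temperature, A2QK against hsfa2 after heat, and 3 differences between heat responses. Adjusted p-values are limma's with Benjamini-Hochberg adjustment within a comparison, two-sided, and a probe set was called raised or lowered at an adjusted p under 0.05. Errors of log2 changes are standard errors of this fit, and errors of group levels are SDs of 2 arrays. Shares were taken of probe sets raised at least 2-fold by heat in WT, with Wilson intervals at 95% that cover counting of probe sets only. Where both comparisons of a share or overlap used the same arrays, 20 simulations with an unchanged group were run. The whole group was unchanged and noise was drawn independently for each array, so they show only how often an unchanged group is called. They do not give the overlap that shared arrays produce among called probe sets. Overlaps were tested with Fisher's exact test, although genes are not independent.

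Gene lists were written from textbook knowledge before the data were examined: 20 lists with 287 members, of which 52 were measured through a single-gene probe set. The lists are heat shock factors, small heat shock proteins, HSP70 and HSP110, HSP90 and HSP100, chaperonins, co-chaperones, other heat-tolerance genes, endoplasmic reticulum folding, antioxidant enzymes, abscisic acid with drought and cold, jasmonate, salicylic acid with defence, auxin response, expansins with cell wall loosening, photosynthesis, cell cycle, circadian clock, root markers, seed and embryo markers, and reference genes. The 8 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They held 9 of 17 small heat shock proteins, 8 of 13 co-chaperones, 4 of 15 endoplasmic reticulum folding genes and 3 of 12 auxin genes. The others held 5 of 22 abscisic acid, drought and cold genes, 3 of 10 expansins and cell wall genes, 3 of 26 photosynthesis genes and 3 of 9 reference genes. A test speaks only for the measured members. The estimated correlation, like the SEs, came from the residuals of all arrays, so arrays outside a comparison enter its tests. For the small heat shock proteins these include the heated QK arrays, which lay far apart. Plastid-encoded, mitochondrion-encoded and embryogenesis genes were grouped only after the data were seen, because such genes stood at the top of comparisons, so they are described by counts and medians without a test. Genes near either end of the arrays' scale have compressed differences.

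Genes were named by a rule set before the data were examined: the 5 disrupted or added factors; in each comparison up to 10 of the largest rises and 10 of the largest falls among called single-gene probe sets whose arrays did not overlap between the groups; and members of the lists, chaperones first. Alternatives set beforehand were a further quantile normalization, equal array medians, leaving out the dimmest probe sets, leaving out probe sets marked as possibly cross-hybridising, a 2-fold minimum, eBayes with trend and robust options, the replicate number as a block, a fit of the compared groups alone, and leaving out each array in turn. Subtracting the difference of hsfa2 from WT, using WT and QK arrays of a single number, and blocking the number within WT and QK were added after the data were seen, as was the count of an overlap apart from genes that moved alike in hsfa2 against WT.

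Same-numbered arrays were compared by the correlation, across probe sets, of their deviations from the group means. The 6 pairs within WT and QK gave r of 0.535 to 0.795, and the other 22 pairs, which involve hsfa2 or A2QK, gave -0.0221 to 0.152. The numbers come from the labels, which do not say what they mark; they paired the arrays of WT and QK but not those of hsfa2 and A2QK. Values within number 1 and within number 2 are therefore given for comparisons of WT and QK.

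The fit was tested on simulated data with 100 probe sets changed by each size among 22746. For the heat response in WT it recovered 41% of changes of 1 and 90% of changes of 2 on the log2 scale, with 3.68% false calls. For QK against WT at 22 °C it recovered 34% and 95%, with 7.19% false calls, and for the heat response of A2QK against that of QK 10% and 75%, with 4.49% false calls. The simulated noise was independent, with the same SD in all groups. In the data the spread differed between groups (root mean square SD 0.463 in WT and 0.174 in A2QK at 22 °C), and WT and QK arrays deviated together. These rates may therefore not carry over to the data. Plots were drawn with matplotlib 3.10.9.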

Results

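Transcript levels were compared between WT, hsfa2, QK and A2QK seedlings of Arabidopsis at 22 °C and after 1 h at 37 °C, with 2 arrays for each of the 8 groups. HSFA1 and HSFA2 proteins are transcription factors that activate heat shock genes. The study asked which heat-responsive genes lean more on the HSFA1 group and which on HSFA2: the hsfa2 line lacks the latter, QK lacks the former, and A2QK adds HSFA2 back to plants without the 4 HSFA1 genes. The heat shock factor, HSP90 and HSP100, and seed marker lists had 0 measured members of 21, 9 and 12, and their genes are not analysed here.

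Heat raised the chaperone genes of WT seedlings by the widest margins among named genes. HSP17.6C (AT1G53540), a cytosolic small heat shock protein, went from 2.95 ± 0.20 to 12.94 ± 0.14 (log2, SD, n = 2), a change of 9.99 ± 1.26 (log2 ± SE, as for all changes here; adjusted p = 0.000401). HSP26.5 (AT1G52560), HSP22 (AT4G10250), HSP17.6B (AT2G29500) and HSP15.7 (AT5G37670) rose by 9.39, 8.54, 8.49 and 8.12. Of the 9 measured small heat shock proteins 7 rose, with a list median of 8.12, while HSP15.4 (0.07 ± 0.40) and HSP14.7 (-0.01 ± 0.20) did not pass. Of 8 co-chaperones, which assist HSP70 and HSP90, 6 rose with a list median of 4.67, among them HOP3 (7.34 ± 0.75), DNAJ-like (6.58 ± 0.53), ROF2 (6.32 ± 0.81) and FES1A (6.08 ± 0.53), and HOP1 (0.14 ± 0.26) and P23-1 (0.27 ± 0.22) did not pass.

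Other protein folding genes rose with them in WT: both HSP70 members, HSC70-2 by 2.34 ± 0.40 and HSC70-3 by 2.89 ± 0.68, the single chaperonin CPN60B2 by 3.29 ± 0.51, and HSA32, a gene of lasting heat tolerance, by 4.93 ± 0.28. AT1G71000, which encodes a DnaJ-domain protein, rose by 8.23 ± 0.45, and nad6, a mitochondrion-encoded subunit of respiratory complex I, rose by 6.80 ± 0.19. The falls were smaller, and the largest among named genes included AT5G54370 (-3.04 ± 0.37), PR-1-LIKE (-2.81 ± 0.35), AT5G64110 (-2.77 ± 0.38), the subtilase gene SBT4.12 (-2.73 ± 0.24) and the beta-glucosidase gene BGLU33 (-2.37 ± 0.20). The endoplasmic reticulum folding list had 0 of 4 members called (median 0.10; camera adjusted p = 0.78).

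In WT 1965 probe sets passed, 753 raised and 1212 lowered, and 500 were raised at least 2-fold. The small heat shock proteins stood apart from other genes (camera adjusted p = 2.45e-11), a call that was lost with an estimated correlation (adjusted p = 0.0558); the co-chaperones passed both ways (adjusted p = 8.2e-12, and 0.0146 with an estimated correlation). Adjusted over the list alone, the counts were again 7 and 6. HSP17.6C rose by 9.75 within number 1 and by 10.23 within number 2, and HOP3 by 8.34 and 6.35. The levels of HSP17.6C lie near both ends of the arrays' scale, so its change is a lower bound. Setting the array medians equal moved the median of all changes to 0.144 and the split to 1052 raised and 793 lowered, so that 57% instead of 38.3% of calls were rises. The count was 1049 without WT heat replicate 1, 232 with the WT arrays fitted alone, and 3652 with the number as a block within WT and QK.

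The other fixed lists had few calls with heat in WT. IAA29, of the auxin-inducible repressor family, rose by 0.62 ± 0.16, whereas the auxin-conjugating enzyme genes GH3.3 (0.55 ± 0.27) and GH3.5 (0.01 ± 0.40) did not pass (list camera adjusted p = 0.15). Abscisic acid, drought and cold genes had 0 of 5 called (median 0.52, adjusted p = 0.21; 1 adjusted over the list alone), expansins and cell wall loosening 0 of 3 (median -0.81, adjusted p = 0.437), photosynthesis 0 of 3 (median -0.37, adjusted p = 0.14) and reference genes 0 of 3 (median 0.12, adjusted p = 0.78). Too few members were measured to test the remaining lists. ZAT10 (1.02 ± 0.62) of the heat-tolerance list, the ascorbate peroxidases SAPX (-0.06 ± 0.19) and TAPX (0.26 ± 0.16), the jasmonate marker PDF1.2 (0.28 ± 0.20) and the defence gene SAG101 (-0.02 ± 0.23) did not pass, nor did the Aurora kinases AUR1 (0.45 ± 0.16) and AUR2 (0.45 ± 0.32), the clock gene GI (-0.24 ± 1.01) or the root hair expansins EXPA7 (-0.90 ± 0.28) and EXPA18 (-1.27 ± 0.38); adjusted over the list alone, 1 cell cycle gene was raised and 2 root markers and 1 reference gene were lowered.

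**Figure D1:**
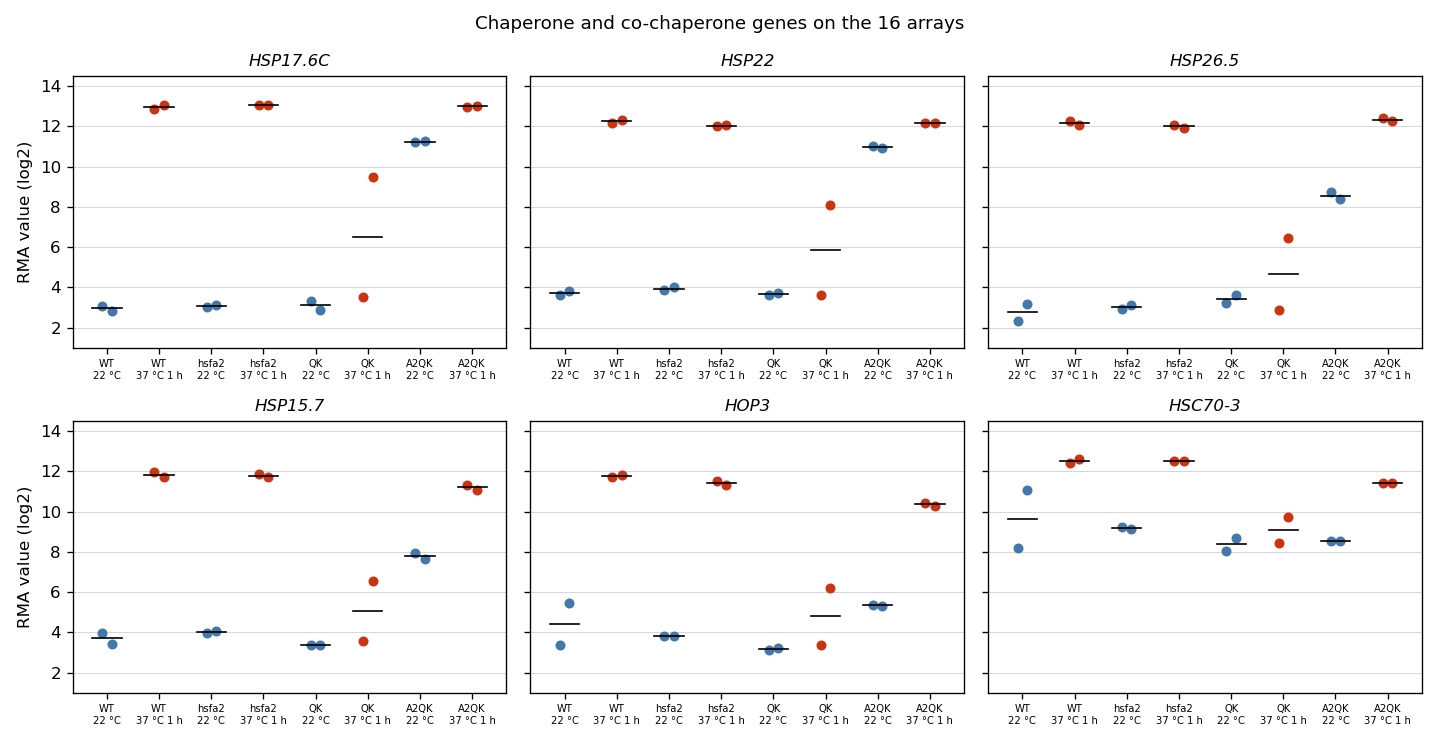
Log2 RMA values of 6 chaperone and co-chaperone genes on the 16 arrays, by genotype and temperature. Points are arrays (blue, 22 °C; red, 1 h at 37 °C) and bars are group means; in A2QK at 22 °C HSP17.6C lay at 11.23 and HSP22 at 10.99, and the 2 heated QK arrays lay far apart for the small heat shock proteins.

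The hsfa2 seedlings raised the same classes of chaperones. HSP17.6C rose by 9.99 ± 1.26 and ended at 13.06 ± 0.01 against 12.94 ± 0.14 in WT, and AT1G71000, HSP26.5, HSP23.5, ROF2 and DNAJ-like rose by 9.17, 8.98, 8.90, 8.24 and 8.04. Both end levels of HSP17.6C lie near the top of the arrays' scale, so they do not show that the lines were equal. Of the small heat shock proteins 7 of 9 rose (median 8.11; 8 adjusted over the list alone), and of the co-chaperones 6 of 8 (6 adjusted over the list alone). ZAT10, a zinc finger repressor, rose by 2.17 ± 0.62, IAA29 fell by 1.00 on the log2 scale, and the steepest falls among named genes were those of AT4G36180 and BGLU33 (-3.02 ± 0.20). The reference gene SAND was lowered by heat here (-0.61 ± 0.14, adjusted p = 0.0163).

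In hsfa2 3171 probe sets passed, 1277 raised and 1894 lowered. Camera gave adjusted p = 3.73e-10 for the small heat shock proteins (adjusted p = 0.0735 with an estimated correlation) and 1.99e-10 for the co-chaperones (adjusted p = 0.0216 with an estimated correlation). The heat response differed between hsfa2 and WT at a single probe set by limma, which the annotation does not list with a gene (2.23 ± 0.25, adjusted p = 0.035), and 1091 probe sets had an unadjusted p under 0.05. The co-chaperone list responded slightly more in hsfa2 than in WT (median 0.43, camera adjusted p = 0.016), a call lost with an estimated correlation (adjusted p = 0.332). Equal array medians moved the median of all hsfa2 changes to 0.212 and the share of rises among calls from 40.3% to 68.4%. The count was 1620 and 1471 without hsfa2 22 °C replicate 1 and 2 and 2019 without hsfa2 heat replicate 2, and the single call between the lines was 0 without any of 11 of the 16 arrays.

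In QK, which lacks the 4 HSFA1 factors, heat lowered many of the genes it lowered in WT and raised fewer of those it raised there. Of 988 probe sets lowered in QK 634 were also lowered in WT (52.6 for independent lists), and of 573 raised 182 were also raised (19.0). The largest rises in QK included transcripts encoded in the mitochondrion, nad6 (7.14 ± 0.19), nad5 (6.41 ± 0.34), nad1 (5.34 ± 0.29), nad9 (5.24 ± 0.14) and cox2 (4.75 ± 0.23), which code for respiratory chain subunits. None of the 9 small heat shock proteins passed: their median was 2.19, and HSP17.6C changed by 0.21 within number 1 and 6.62 within number 2, with heated arrays at an SD of 4.22. Of the co-chaperones 0 of 8 passed over all probe sets, and 5 when adjusted over the list alone (median 0.99). HSA32 rose by 1.03 ± 0.28. AT5G54370 (-3.84 ± 0.37), AT1G64380 (-3.46 ± 0.65) and SBT4.12 (-2.76 ± 0.24) fell.

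Genes for folding in the endoplasmic reticulum rose with heat in QK: the calreticulin CRT2 (AT1G09210) by 2.59 ± 0.36, the DnaJ co-chaperone ERDJ3B (AT3G62600) by 2.19 ± 0.20 and the calnexin CNX2 (AT5G07340) by 1.36 ± 0.30, while BZIP60, a regulator of the unfolded protein response, did not pass (0.15 ± 0.23). The auxin genes IAA29 (2.75 ± 0.16) and GH3.3 rose too, as did the cell wall gene XTH33 (2.48 ± 0.28), and SAG101 (-1.08 ± 0.23) and EXPA7 (-1.29 ± 0.28) fell.

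In QK 1561 probe sets passed, 573 raised and 988 lowered. Camera gave adjusted p = 7.4e-05 for endoplasmic reticulum folding and 3.88e-05 for auxin response, and both held with an estimated correlation (adjusted p = 0.0133 for each). For the small heat shock proteins (adjusted p = 0.000346) and co-chaperones (adjusted p = 0.000395) the call was lost with an estimated correlation (adjusted p = 0.239 and 0.118). Equal array medians moved the rises among calls from 36.7% to 48.1%. The count was 904 and 942 without QK heat replicate 1 and 2, 42 with the QK arrays fitted alone, and 3408 with the number as a block within WT and QK.

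Set directly against WT, the heat response of QK was smaller for many measured chaperones and larger for 2 of the 4 measured endoplasmic reticulum folding genes, from a list of 15. HSP26.5 (-8.15 ± 1.12, adjusted p = 0.00233), HSP15.7 (-6.42 ± 0.93), HSP22 (-6.34 ± 1.34) and HSP17.6B (-6.17 ± 1.12) responded less, so that 4 of 9 small heat shock proteins passed and 7 when adjusted over the list alone. HSP17.6C gave -6.58 ± 1.78 and did not pass (adjusted p = 0.147). Of the co-chaperones 5 of 8 responded less, HOP3 (-5.71 ± 1.06), DNAJ-like (-4.83 ± 0.74), FES1A (-4.64 ± 0.75), SGT1A (-2.71 ± 0.31) and HOP2 (-1.97 ± 0.21), and so did HSA32 (-3.90 ± 0.39). Outside the lists AT1G71000 (-7.20 ± 0.64), AT1G21550 (-6.14 ± 0.54), AT1G10260 (-5.79 ± 0.24) and AT1G66080 (-5.53 ± 0.39) responded less.

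Larger responses in QK than in WT were seen for CRT2 (2.43 ± 0.50), ERDJ3B (1.89 ± 0.29) and IAA29 (2.12 ± 0.23), for XTH33 (2.71 ± 0.39) and WAG2 (2.61 ± 0.28), a kinase gene of auxin transport, and for AT5G44060 (3.03 ± 0.26). IAA29 started lower in QK than in WT, by -1.86 and -1.99 at 22 °C within number 1 and 2, and differed by -0.04 and 0.43 after heat. CRT2 differed by 0.12 and 0.61 at 22 °C and by 2.78 and 2.80 after heat. The endoplasmic reticulum list had 2 of 4 members called (3 adjusted over the list alone), with a median of 1.61; CNX2 gave 1.33 ± 0.42 and BZIP60 0.45 ± 0.32. Within number 1 the difference was 2.66 for CRT2 and 1.92 for ERDJ3B, and within number 2 it was 2.19 and 1.87. For HSP26.5 it was -10.24 and -6.07.

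The 2 heat responses differed at 343 probe sets, 102 larger and 241 smaller in QK. Camera passed for the small heat shock proteins (adjusted p = 8.4e-11), co-chaperones (7.44e-13), endoplasmic reticulum folding (6.67e-07) and auxin response (2.75e-06), and each held with an estimated correlation (adjusted p = 0.0315, 0.00372, 0.00372 and 0.00372). With the number as a block within WT and QK 638 probe sets passed, and 89 with the WT and QK arrays fitted alone.

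**Figure D2:**
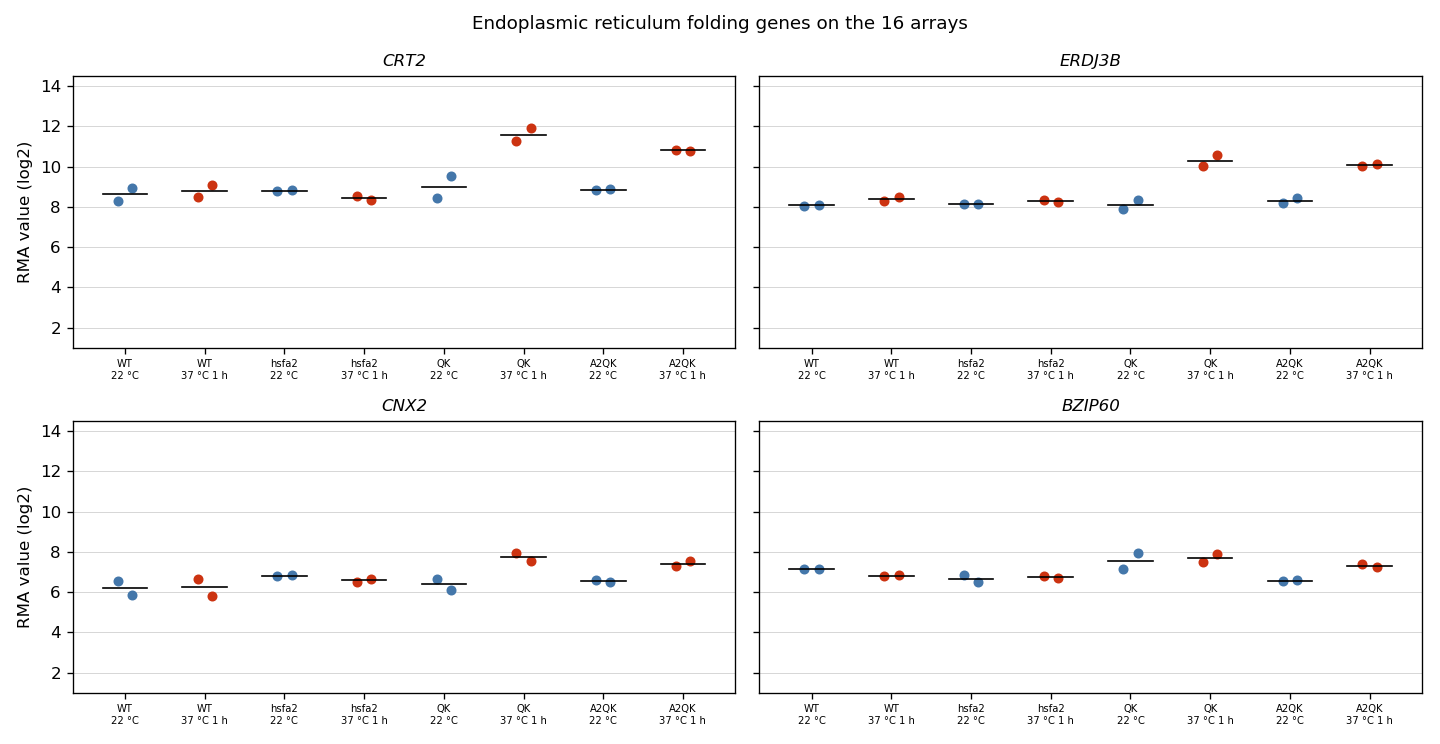
Log2 RMA values of the 4 measured endoplasmic reticulum folding genes on the 16 arrays, by genotype and temperature (blue, 22 °C; red, 1 h at 37 °C; bars, group means). CRT2 reached 11.58 in heated QK and 10.80 in heated A2QK, against 8.79 in heated WT.

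In A2QK, where HSFA2 is expressed without the HSFA1 factors, heat raised chaperones again. HSP17.4III (6.91 ± 0.94), AT1G21550 (6.71 ± 0.38), nad6 (6.64 ± 0.19), AT1G71000 (6.35 ± 0.45) and HSP23.5 (5.68 ± 0.88) rose furthest among named genes. Of the small heat shock proteins 4 of 9 rose, adding HSP26.5 (3.76 ± 0.79) and HSP15.7 (3.42 ± 0.66), and HSP17.6C, already at 11.23 ± 0.02 without heat, gave 1.76 ± 1.26. Of the co-chaperones 6 of 8 rose, led by HOP3 (5.01 ± 0.75) and FES1A (4.32 ± 0.53). CRT2 (1.95 ± 0.36), ERDJ3B (1.77 ± 0.20) and BZIP60 (0.75 ± 0.23) rose, as in part they did in QK, and the auxin genes GH3.3 and GH3.5 (1.67 ± 0.40), the dehydrin LTI30 (1.68 ± 0.49) and XTH33 (1.78 ± 0.28) rose, while AT5G02140 (-3.28 ± 0.24), AT1G01300 (-3.21 ± 0.42) and the root hair expansin EXPA18 (-1.97 ± 0.38) fell.

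In A2QK 3593 probe sets passed, 1498 raised and 2095 lowered. Camera passed for co-chaperones (adjusted p = 5.36e-07), endoplasmic reticulum folding (0.000617) and auxin response (0.00403), each also with an estimated correlation (adjusted p = 0.0342, 0.0342 and 0.038), and for small heat shock proteins (0.000617), which lost it (adjusted p = 0.264 with an estimated correlation). Equal array medians moved the median of all changes to 0.188 and the rises among calls from 41.7% to 66.2%. The count was 1770 and 1929 without A2QK 22 °C replicate 1 and 2, 2132 and 1843 without A2QK heat replicate 1 and 2, and 7387 with the A2QK arrays fitted alone.

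The heat response of A2QK exceeded that of QK by wide margins for AT1G21550 (6.39 ± 0.54), AT1G71000 (5.32 ± 0.64), AT5G05220 (5.28 ± 0.40) and AT5G53680 (4.33 ± 0.33). The co-chaperones SGT1A (2.64 ± 0.31) and HOP2 (1.42 ± 0.21) responded more in A2QK, and 5 of 8 did when adjusted over the list alone. No small heat shock protein passed (median -0.15, mean 0.81, camera adjusted p = 0.534). IAA29 (-2.40 ± 0.23) and the mitochondrion-encoded matR (-2.41 ± 0.26) and nad1 (-2.12 ± 0.41) responded less. In all 459 probe sets passed, 373 larger and 86 smaller in A2QK; the co-chaperone call (camera adjusted p = 3.61e-05) was lost with an estimated correlation (adjusted p = 0.15). The count was 231 and 211 without A2QK 22 °C replicate 1 and 2, and 222 and 258 without A2QK heat replicate 1 and 2.

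Without heat the hsfa2 seedlings differed from WT most at a pair of cold-regulated chloroplast proteins. COR15A was at 10.75 ± 0.12 in hsfa2 and 4.23 ± 0.89 in WT, a difference of 6.52 ± 0.40 (adjusted p = 4.36e-05), and COR15B was higher by 6.04 ± 0.82. Plastid-encoded transcripts moved both ways: ycf3 (4.43 ± 0.47), rpl14 (3.40 ± 0.89) and ndhJ (3.17 ± 0.56) were higher, and psaC, a photosystem I subunit, was lower (-3.73 ± 0.40). The defensin gene PDF2.1 (3.62 ± 0.64) was higher, AT5G15780 (-3.14 ± 0.55) and AT4G34150 (-3.06 ± 0.33) were lower, and the 3 auxin genes IAA29 (-0.84 ± 0.16), GH3.3 (-1.20 ± 0.27) and GH3.5 (-1.95 ± 0.40) were lower. Of the chaperones HSP14.7 (-0.87 ± 0.20) and SGT1A (-1.38 ± 0.22) were lower and the other small heat shock proteins and co-chaperones did not pass.

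Among named genes the difference after heat kept COR15A (6.61 ± 0.40), COR15B (5.86 ± 0.82) and ycf3 at its top, and ATATH8 (-3.76 ± 0.36), psaC (-3.60 ± 0.40), AT4G17250 (-3.19 ± 0.28), the methionine lyase gene MGL (-2.59 ± 0.19) and the SUMO ligase gene SIZ1 (-2.51 ± 0.38) at its bottom. None of the 9 small heat shock proteins passed against WT (median -0.05, camera adjusted p = 0.867), and of the co-chaperones HOP2 alone passed (0.79 ± 0.15). The SEs of the small heat shock proteins are pooled with the heated QK arrays, which lay far apart, and heated HSP17.6C lay near the top of the arrays' scale. The lack of calls therefore does not show equal levels. IAA29 (-2.47 ± 0.16) and GH3.3 (-1.22 ± 0.27) were lower.

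The lines differed at 1796 probe sets at 22 °C, 905 higher and 891 lower in hsfa2, and at 1822 after heat, 950 and 872. Auxin response passed camera at 22 °C (adjusted p = 0.00158) and after heat (0.000217), also with an estimated correlation (adjusted p = 0.0444 and 0.0227), and the abscisic acid, drought and cold list, through COR15A and COR15B, passed only without it (adjusted p = 0.0168 and 0.0459, against adjusted p = 0.139 and 0.221 with an estimated correlation). WT arrays deviated together with QK arrays and not with hsfa2 arrays: of the probe sets called here at 22 °C, 845 changed the same way in A2QK against QK, where independent lists give 81.7, and 8 changed oppositely, where they give 81.6. The counts were 648 and 424 at 22 °C without hsfa2 22 °C replicate 1 and 2, and after heat 733, 645 and 809 without WT heat replicate 1, WT heat replicate 2 and hsfa2 heat replicate 2. With these 2 groups fitted alone 0 probe sets passed limma at 22 °C (3902 at an unadjusted p under 0.05) and 1 after heat, and equal array medians moved the median of all changes after heat to 0.116 and the higher share from 52.1% to 67.3%.

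Without heat, QK differed from WT at named genes in both directions. AT3G17520 (5.74 ± 0.79), BGLU19 (5.36 ± 0.73), AT2G28490 (5.15 ± 0.60), M17 (4.97 ± 0.60) and LEA18 (4.72 ± 0.80) were higher than in WT; LEA18 belongs to the late embryogenesis abundant proteins, and no member of the fixed seed list was measured. AT3G47250 (-5.69 ± 0.23, adjusted p = 5.39e-07), AT1G23130 (-4.65 ± 0.42) and AT1G23960 (-4.52 ± 0.22) were lower. Before heat the co-chaperone SGT1A was lower (-1.23 ± 0.22), with 4 of 8 co-chaperones lower when adjusted over the list alone, and IAA29 was lower (-1.93 ± 0.16), whereas SAG101 was higher (1.28 ± 0.23). The co-chaperone differences were uneven between the array numbers. Within number 1 and number 2 SGT1A differed by -0.68 and -1.78, HOP3 by -0.25 and -2.25 and ROF2 by -0.95 and -3.53. P23-1 fell more within number 1 (-1.23 and -0.55), and HOP2 alike in both (-0.30 and -0.27).

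After heat the largest falls of QK against WT among named genes were those of AT1G71000 (-7.50 ± 0.45), HSP26.5 (-7.47 ± 0.79), HSP23.5 (-7.39 ± 0.88) and HOP3 (-6.96 ± 0.75), which are chaperones or assist them, and of AT1G21550 (-6.78 ± 0.38), which is in no chaperone list. Of the small heat shock proteins 7 of 9 were lower and of the co-chaperones 6 of 8 (7 and 7 adjusted over the list alone, with 2 small heat shock proteins then higher), as were HSC70-2 (-3.51 ± 0.40), HSC70-3 (-3.42 ± 0.68), CPN60B2 (-4.00 ± 0.51) and HSA32 (-4.17 ± 0.28). The 4 endoplasmic reticulum genes were higher, CRT2 by 2.79 ± 0.36 and BZIP60 by 0.87 ± 0.23. BGLU19 (6.51 ± 0.73), M17 (6.23 ± 0.60), LEA18 (6.02 ± 0.80) and ICL (5.51 ± 0.50), the isocitrate lyase of the glyoxylate cycle, were higher, and so was LEA4-5 (3.45 ± 0.83).

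At 22 °C 498 probe sets passed, 277 higher and 221 lower in QK, and after heat 1707, 949 and 758. After heat camera passed for co-chaperones (adjusted p = 1.14e-12) and endoplasmic reticulum folding (4.86e-06), both with adjusted p = 0.00705 with an estimated correlation, and for small heat shock proteins (5.41e-07), which lost it (adjusted p = 0.115 with an estimated correlation). At 22 °C it passed for auxin response (adjusted p = 0.00012, and 0.0234 with an estimated correlation) and for co-chaperones (4.37e-05, but adjusted p = 0.078 with an estimated correlation). BGLU19 at 22 °C differed by 5.32 within number 1 and 5.39 within number 2, and AT3G47250 by -5.48 and -5.90; after heat HSP26.5 differed by -9.35 and -5.60. Without WT 22 °C replicate 2 the count at 22 °C was 272, and with these groups fitted alone it was 0 (1405 at an unadjusted p under 0.05) and after heat 431. With the number as a block within WT and QK the counts were 1611 and 3381, and equal array medians moved the median of all changes after heat to -0.127 and the higher share from 55.6% to 41.1%.

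HSFA2 expressed in QK went with high small heat shock protein levels without heat. HSP17.6C lay at 11.23 ± 0.02 in A2QK and near the floor in QK at 22 °C, a difference of 8.13 ± 1.26 (adjusted p = 0.00284) that can be read only as a lower bound, and HSP22 (7.31 ± 0.95), HSP17.6B (5.95 ± 0.80), HSP26.5 (5.12 ± 0.79) and HSP15.7 (4.41 ± 0.66) were higher, 5 of 9 in all and 7 adjusted over the list alone. Of the co-chaperones ROF2 (4.11 ± 0.81), DNAJ-like (2.70 ± 0.53), P23-1 (0.89 ± 0.22) and HOP2 (0.64 ± 0.15) were higher and SGT1A (-1.14 ± 0.22) was lower, and HSA32 was higher (2.25 ± 0.28). HOP3 (2.19 ± 0.75) and HSP23.5 (3.04 ± 0.88) did not pass, and AT1G71000 lay at 2.97 ± 0.15 in A2QK. AT1G73600 (4.76 ± 0.28) was higher, and psaC (-4.12 ± 0.40), AT5G15780 (-3.58 ± 0.55), AT1G64380 (-3.46 ± 0.65) and SIS (-3.45 ± 0.33) were lower; TAPX (0.64 ± 0.16), AUR1 (0.59 ± 0.16) and COR15A (2.25 ± 0.40) were higher, and BZIP60 (-0.97 ± 0.23), GH3.5 (-2.09 ± 0.40) and XTH33 (-2.16 ± 0.28) were lower.

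After heat 7 of 9 small heat shock proteins and 6 of 8 co-chaperones were higher in A2QK than in QK, 8 and 6 adjusted over the list alone, among them HSP26.5 (7.64 ± 0.79, adjusted p = 8.04e-05), HSP23.5 (6.53 ± 0.88), HSP17.6C (6.47 ± 1.26) and ROF2 (5.75 ± 0.81). AT1G21550 (7.16 ± 0.38) and AT5G53680 (6.79 ± 0.23) were higher. HSC70-3 (2.32 ± 0.68) and CPN60B2 (1.87 ± 0.51) were higher, psaC (-4.42 ± 0.40), ZW9 (-4.21 ± 1.03), IAA29 (-2.93 ± 0.16) and XTH33 (-2.86 ± 0.28) were lower, and 0 of 4 endoplasmic reticulum genes passed (median -0.35).

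At 22 °C 2068 probe sets passed, 1176 higher and 892 lower in A2QK, and after heat 2803, 1410 and 1393. Camera passed at 22 °C for small heat shock proteins (adjusted p = 5.97e-08), co-chaperones (0.00864) and auxin response (0.00864), and each was lost with an estimated correlation (adjusted p = 0.12, 0.256 and 0.119). After heat small heat shock proteins and co-chaperones passed (adjusted p = 2.67e-08 for each; 0.0754 and 0.041 with an estimated correlation), as did auxin response (0.00253, and adjusted p = 0.041 with an estimated correlation). The difference of hsfa2 from WT was subtracted to remove what the hsfa2 and A2QK arrays share against WT and QK. Any effect of lacking HSFA2 in hsfa2 is subtracted with it and can enlarge or create a difference. What remains is therefore not the effect of the added HSFA2 alone. The subtraction left 41 probe sets at 22 °C and 1062 after heat. At 22 °C HSP17.6C went from 8.13 ± 1.26 to 8.02 ± 1.78 (adjusted p = 0.129), HSP22 from 7.31 ± 0.95 to 7.10 ± 1.34 (adjusted p = 0.07) and HSP23.5 from 3.04 ± 0.88 to 4.75 ± 1.24 (adjusted p = 0.238), with a larger SE because 4 groups entered. These SEs are pooled over all groups, including the heated QK arrays, which lay far apart for the small heat shock proteins. A call lost at 22 °C therefore does not show a small difference there. Of the 9 small heat shock proteins 0 passed at 22 °C and 5 after heat, with 0 and 6 of 8 co-chaperones. HSA32 passed at both temperatures, with 2.48 ± 0.39 at 22 °C (adjusted p = 0.0361). At 22 °C SGT1A turned from -1.14 to 0.24, AUR1 from 0.59 to -0.26 and COR15A from 2.25 to -4.27 (adjusted p = 0.019).

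Other differences of A2QK from QK shrank with the subtraction and were no longer called. The values of hsfa2 against WT for these genes had the same sign. At 22 °C GH3.5 went from -2.09 ± 0.40 to -0.15 ± 0.57, XTH33 from -2.16 ± 0.28 to -0.82 ± 0.39, BZIP60 from -0.97 ± 0.23 to -0.51 ± 0.32 and TAPX from 0.64 ± 0.16 to 0.32 ± 0.23. After heat IAA29 went from -2.93 ± 0.16 to -0.45 ± 0.23 (adjusted p = 0.344), and none of the 3 auxin genes passed (median -0.11). XTH33 passed after heat at -1.92 ± 0.39 (adjusted p = 0.0156).

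Leaving out arrays also lowered these counts. At 22 °C it was 1372, 637 and 527 without QK 22 °C replicate 2 and A2QK 22 °C replicates 1 and 2, and after heat 1773, 1463 and 1334 without QK heat replicate 1 and A2QK heat replicates 1 and 2. With these groups fitted alone the counts were 442 and 1819, and equal array medians moved the higher share after heat from 50.3% to 61%.

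**Figure D3:**
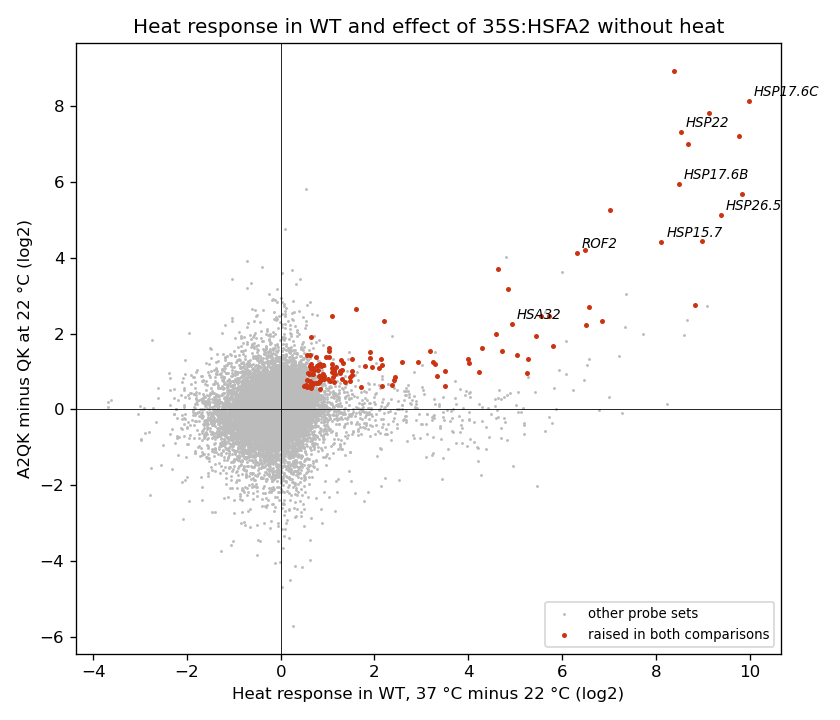
Change of each of 22746 probe sets with heat in WT (horizontal axis, log2) and between A2QK and QK at 22 °C (vertical axis, log2). Red points are the 126 probe sets raised in both comparisons, and HSP17.6C lies at 9.99 and 8.13.

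Between heated A2QK and heated hsfa2 seedlings HSP14.7 passed among the 9 small heat shock proteins (1.35 ± 0.20), and the list median was -0.07 (camera adjusted p = 0.482). HSP26.5 gave 0.32 ± 0.79 and HSP15.7 -0.59 ± 0.66, which does not show equal levels, and HSP17.6C lay close to the top of the arrays' scale in both, at 12.99 and 13.06, so its difference says little. HSC70-2 (-3.01 ± 0.40), CPN60B2 (-1.98 ± 0.51), SGT1A (-1.85 ± 0.22) and HOP2 (-0.99 ± 0.15) were lower in A2QK, and CRT2 (2.35 ± 0.36) and ERDJ3B (1.79 ± 0.20) were higher. AT4G37220 (6.26 ± 0.72), AT2G21820 (5.75 ± 0.28) and LEA18 (4.84 ± 0.80) were the largest differences upward among named genes, and COR15B (-4.99 ± 0.82), COR15A (-4.97 ± 0.40) and AT2G07777 (-4.95 ± 0.28) downward; AUR1 (-0.72 ± 0.16) and the reference gene TIP41 (-0.84 ± 0.18) were lower, GH3.3 (1.29 ± 0.27) was higher.

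Here 3048 probe sets passed, 1724 higher and 1324 lower in A2QK. Camera passed for endoplasmic reticulum folding (adjusted p = 0.00117) and co-chaperones (0.00851), and both calls were lost with an estimated correlation (adjusted p = 0.0514 and 0.338). Equal array medians moved the median of all changes to -0.192 and the higher share from 56.6% to 37%. The count was 1896, 1321 and 1378 without hsfa2 heat replicate 2 and A2QK heat replicates 1 and 2.

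Among the 500 probe sets raised at least 2-fold by heat in WT, 224 (44.8%, Wilson interval 40.5 to 49.2%) had a smaller heat response in QK, HSP26.5, HOP3 and HSA32 among them, and 120 (24%, 20.5 to 27.9%) were raised by heat in QK. In hsfa2 446 (89.2%) and in A2QK 372 (74.4%) of the 500 were raised by heat. After heat 338 (67.6%) were lower in QK than in WT. In hsfa2 43 (8.6%, 6.45 to 11.4%) were lower than in WT and 13 (2.6%) were higher. Over all 22746 probe sets 872 were lower and 950 higher in hsfa2 after heat. These calls may include what the hsfa2 and A2QK arrays share against WT and QK. The 8.6% is therefore not a share known to depend on HSFA2. Simulations with unchanged groups on the shared arrays gave at most 0.159% for the smaller response in QK and 0 for the lower level in hsfa2. The share of 8.6% was 5.05%, 4%, 4.49% and 4.69% without WT heat replicates 1 and 2 and hsfa2 heat replicates 1 and 2.

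Of the 224 probe sets, 50 (22.3%) were higher in A2QK than in QK at 22 °C, 169 (75.4%) after heat, and 54 (24.1%) at neither temperature; HSP22 and HSP17.6B were higher at both, and FES1A and HOP3 after heat. Simulations with A2QK equal to QK gave 0, since almost nothing is called in an unchanged group. The QK arrays are common to these comparisons and 2 arrays cannot be split further, so the part due to sharing is not known. Of the same 224, 27 (12.1%) were lower in hsfa2 than in WT after heat. HOP2, SGT1A, AT1G71000 and AT1G21550 combined a smaller response in QK with a larger one in A2QK than in QK, as did 110 probe sets in all (3.95 for independent lists, 0 in simulations). The QK arrays enter these comparisons with opposite signs, so neither figure gives the number that sharing alone would produce.

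Genes raised by heat in WT overlapped with those higher in A2QK than in QK without heat. Both comparisons raised 126 probe sets, HSP17.6C, HSP22, ROF2 and HSA32 among them, where independent lists give 38.9 (Fisher's exact p = 2.05e-32), and both lowered 125 (47.5; Fisher's exact p = 1.33e-23). Of the 126, 37 were also higher in hsfa2 than in WT at 22 °C; the 738 probe sets higher in A2QK but not called so in hsfa2 held the other 89 (24.4 for independent lists). The 27 still higher in A2QK after the subtraction held 15 (0.894). Probe sets lower in hsfa2 after heat and higher in A2QK than in QK at 22 °C numbered 15. Independent lists would give 45.1. However, these comparisons correlated with r of 0.506 across all probe sets, and same-numbered arrays of heated WT and unheated QK deviated together (r = 0.569), so independence does not hold for this count. Unheated WT and unheated QK arrays deviated together as well (r = 0.535). Heated and unheated WT enter the heat response with opposite signs, so deviations that both share with unheated QK cancel there at least in part. How far the Fisher's exact p-values of the 126 and the 125 still carry this limit is not known. The 126 fell to 82, 50, 44 and 82 without QK 22 °C replicate 1, A2QK 22 °C replicates 1 and 2 and WT heat replicate 1, and the 15 shared with hsfa2 ranged from 4 to 16 over the 16 arrays.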

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

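All of the differences between heat responses below came from the planned comparisons, and the settings that use the array numbers within WT and QK were chosen only after the results were seen. The counts were 1 probe set for hsfa2 against WT, 343 for QK against WT and 459 for A2QK against QK.

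Chaperones and their partners responded less to heat in QK than in WT: HSP26.5 by -8.15, AT1G71000 by -7.20, HSP15.7 by -6.42, HSP22 by -6.34, HSP17.6B by -6.17, HOP3 by -5.71, DNAJ-like by -4.83, FES1A by -4.64, HSA32 by -3.90, SGT1A by -2.71 and HOP2 by -1.97 on the log2 scale. AT1G21550 (-6.14), AT1G10260 (-5.79) and AT1G66080 (-5.53) responded less as well. The 2 heated QK arrays differed widely for the small heat shock proteins: HSP26.5 changed with heat by -0.34 within number 1 and by 2.82 within number 2, and HSP22 by 0.03 and 4.36.

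Larger responses in QK than in WT were measured for AT5G44060 (3.03), the cell wall gene XTH33 (2.71), the kinase gene WAG2 (2.61), the endoplasmic reticulum genes CRT2 (2.43) and ERDJ3B (1.89), and IAA29 (2.12).

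A2QK responded more than QK at AT1G21550 (6.39), AT1G71000 (5.32), AT5G05220 (5.28), AT5G53680 (4.33), SGT1A (2.64) and HOP2 (1.42), and less at matR (-2.41), IAA29 (-2.40) and nad1 (-2.12).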

How the results depend on the processing

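The settings that use the array numbers within WT and QK and the subtraction of hsfa2 against WT were chosen only after the results were seen; the others were planned. With 2 arrays per group the counts depend on single arrays and on the pooled variance, and the cause of each shift was not tested. A further quantile normalization kept 380 of 382 named gene values, equal medians 378, and trend with robust eBayes 371. Of 112 camera tests 35 passed, and 18 with an estimated correlation.

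A 2-fold minimum left 1164 calls for heat in WT, 1637 in hsfa2, 941 in QK and 2070 in A2QK, 892 and 768 for hsfa2 against WT at 22 °C and after heat, 1036 and 1615 for A2QK against QK, and 1548 for A2QK against hsfa2. It left 61 in the overlap of heat in WT with A2QK against QK, 5 in that of hsfa2 with A2QK, and 4.4% lower in hsfa2.

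With the number as a block within WT and QK, heat gave 3652 calls in WT, 5344 in hsfa2, 3408 in QK and 5812 in A2QK. The contrasts gave 4217 and 4087 for hsfa2 against WT, 1611 and 3381 for QK against WT, 4925 and 5182 for A2QK against QK, and 5159 for A2QK against hsfa2. Differences of heat responses gave 8 for hsfa2, 638 for QK and 1300 for A2QK, the overlaps 278 and 39, and the shares 57% smaller in QK, 14.74% lower in hsfa2 and 35.7% raised in QK. The plain replicate block gave 2 for the hsfa2 difference of responses.

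With the compared groups alone, heat gave 232 in WT, 42 in QK and 7387 in A2QK, hsfa2 against WT 0 (limma, 3902 at an unadjusted p under 0.05) and 1, QK against WT 0 (limma, 1405) and 431, A2QK against QK 442 and 1819, the QK difference of responses 89, and 225 of 382 named values passed.

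With WT and QK arrays numbered 1, heat gave 5577 in hsfa2 and 6185 in A2QK, hsfa2 against WT 3939 and 3114, QK against WT at 22 °C 766, A2QK against QK 4156 and 4632, A2QK against hsfa2 5583, and the differences of responses 2 for hsfa2, 557 for QK and 1429 for A2QK. The hsfa2 overlap was 36 and the share lower in hsfa2 11.6%. With those numbered 2, heat gave 5577 and 6185, hsfa2 against WT 4616 and 4169, QK against WT at 22 °C 2114, A2QK against QK 4287 and 4549, A2QK against hsfa2 5583, and the differences 13 for hsfa2 and 912 for A2QK. The hsfa2 overlap was 50, and the shares were 40.4% smaller in QK, 16.1% lower in hsfa2 and 34% raised in QK. In these settings lone WT and QK arrays take their variance from the hsfa2 and A2QK groups, whose replicates lay closer together.

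Subtracting hsfa2 against WT left 41 and 1062 calls for A2QK against QK and 26 of 63 named values. It turned SGT1A to 0.24, COR15A to -4.27 and AUR1 to -0.26 at 22 °C, and COR15A to -4.91 after heat. Without the dimmest probe sets the hsfa2 difference of responses had 0 calls by limma (542 at an unadjusted p under 0.05). Equal medians gave 8 for the hsfa2 overlap and shares of 38.9% smaller in QK and 6.06% lower in hsfa2. Without possibly cross-hybridising probe sets 18.22% were raised in QK.

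Leaving out single arrays gave ranges of 1049 to 2076 for heat in WT, 1471 to 3383 in hsfa2, 904 to 1794 in QK and 1770 to 3900 in A2QK. For hsfa2 against WT they were 424 to 1981 and 645 to 2063, for QK against WT 272 to 634 and 1143 to 1919, for A2QK against QK 527 to 2467 and 1334 to 3128, and for A2QK against hsfa2 1321 to 3295. Differences of responses ranged from 0 to 2 for hsfa2, 256 to 384 for QK and 211 to 549 for A2QK. The overlaps ranged from 44 to 135 and 4 to 16, the shares from 36.8 to 44.8% smaller in QK, 4 to 10.2% lower in hsfa2 and 19.6 to 28.4% raised in QK, and the named values that passed from 342 to 370.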

Other observations

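The groups of organelle-encoded and embryogenesis genes, and the tests of explanations here other than that for Ws segments, were chosen only after the results were seen, although the normalization settings they use were planned, and the groups are described without a test. Transcripts encoded in the mitochondrion rose with heat in each genotype: of 15 such genes 14 rose in WT, 11 in hsfa2, 13 in QK and 13 in A2QK, with medians of 3.68, 2.93, 4.14 and 3.22 (14, 12, 13 and 14 adjusted over the list alone). They code mostly for respiratory complexes and cytochrome c maturation, and cox1 rose by 4.03 in WT. The 15 were picked by gene symbol from probe sets not matched to RefSeq, and whether the probes also detect nuclear copies was not tested. Probe sets listed with the nuclear loci AT2G07722 and AT2G07741 rose in QK as well, by 5.33 and 4.57 within number 1 and by 6.27 and 5.42 within number 2. Whether they detect transcripts of these loci or mitochondrial ones was not tested, so they are not counted as separate nuclear genes. After heat 8 of the 15 were lower in A2QK than in QK (12 adjusted over the list alone; median -1.17), matR by -2.52 and nad9 by -1.32.

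Plastid-encoded genes differed between hsfa2 and WT at 22 °C, 12 of 69 higher and 2 lower (15 and 4 adjusted over the list alone; median 0.88), and psaJ was lower beside psaC (-2.18). In A2QK against hsfa2 after heat 19 of 69 were lower (21 adjusted over the list alone; median -1.10). Embryogenesis genes, which are normally active in ripening seeds, were grouped because such genes stood at the top of QK against WT, and 4 of 7 were higher at 22 °C (7 adjusted over the list alone; median 2.25) and 5 after heat (6 adjusted over the list alone; median 3.45). OLEO3, an oil body protein, was higher at 22 °C (adjusted p = 0.0296) and LEA by 3.96 after heat, and of the 277 probe sets higher in QK at 22 °C 107 were lower in A2QK than in QK (10.9 for independent lists, 0 in simulations). The QK arrays enter both comparisons with opposite signs, so neither figure gives the number that sharing alone would produce. A probe set that the annotation does not list with a gene, picked after its values were seen, rose with heat in WT by 8.69 ± 0.83 and in hsfa2 by 0.78 ± 0.83, and was lower in hsfa2 than in WT after heat (-8.02 ± 0.83, adjusted p = 0.000661), although the difference of these responses did not pass (-7.91 ± 1.18, adjusted p = 0.127). It changed by 2.49 ± 0.83 in QK, where the heated arrays had an SD of 2.56, and was higher by 7.00 ± 0.83 in A2QK than in QK at 22 °C. Without a gene name these values cannot tell a gene that depends on HSFA2 from HSFA2 itself, for which no probe set was listed.

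At 22 °C the differences of hsfa2 from WT and of A2QK from QK shared 845 probe sets changed the same way, COR15A and psaC among them, against 81.7 for independent lists. An action of HSFA2 on the same genes in both lines, absent in hsfa2 and added in A2QK, would turn them in opposite directions, and 8 did so. Genes called only in A2QK against QK, such as HSP17.6C and HSP22, need not change in hsfa2 at 22 °C. The count of 8 therefore does not test an action of the added HSFA2 on such genes. The count stayed at 802 or more under other normalizations, which argues against differences in the arrays' overall distribution as the source. Both settings start from values already summarized by RMA, so they cannot test whether the arrays went through RMA in separate sets. The count ranged from 279 without A2QK 22 °C replicate 2 to 849 when single arrays were left out. An array set, with hsfa2 and A2QK handled apart from WT and QK, could give much of this pattern but not COR15A in full, which differed by 6.52 in hsfa2 and 2.25 in A2QK and stayed called after the subtraction (-4.27, adjusted p = 0.019), as did 2 others of the 845. For the rest the genotypes cannot be told apart from such a set, and whether cultures or arrays were handled apart stays open, while a set effect of the size seen in hsfa2 against WT leaves the A2QK value of HSA32 (2.25 ± 0.28, then 2.48 ± 0.39 after subtraction).

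The endoplasmic reticulum folding genes CRT2 and ERDJ3B responded to heat in QK more than in WT. The list median of 1.61 was 1.54 at the lower of the other normalizations, which argues against differences in the arrays' overall distribution. The RMA step itself cannot be tested from summarized values. Within the array numbers the median was 1.54 and 1.68. Deviations shared by same-numbered WT and QK arrays cancel in this difference, so such a batch could not produce it. All 343 called differences between these heat responses, CRT2 and ERDJ3B among them, stayed called with the number as a block within WT and QK. That block leaves the differences themselves unchanged and only takes shared deviations out of the spread, so it adds no separate support. A Ws variant that acts alike at both temperatures would show without heat, where the median was 0.27 against 1.71 after heat. Whether the rise comes from the loss of the HSFA1 factors or from a Ws allele that acts only in heat stays open.

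The 498 probe sets that differ between QK and WT at 22 °C, AT3G47250 and BGLU19 among them, could come partly from Ws segments in the mixed background of QK. Called genes lay near each other 1.19 times as often as in random orders, against 1.13 for heat in WT; the criterion written beforehand was met, but by less than the spread of random orders (SD 0.1). Lowered genes gave 1.89 (permutation p = 0.002, 1 of 15 such tests, a split made after the result was seen), against 1.06 for genes lowered by heat in WT, 1.24 for those lower in hsfa2, 1.19 for those lower in A2QK and 1.68 for those raised by heat in WT, and raised genes gave 0.92 (permutation p = 0.706). The smaller and larger within-number values had a median ratio of 0.73, which decides nothing, since the called probe sets were chosen for a small spread. Deviations shared by same-numbered WT and QK arrays cancel in QK minus WT, so such a batch could not produce these differences. All 498 stayed called with the number as a block within WT and QK. That block leaves the differences themselves unchanged and only takes shared deviations out of the spread, so it adds no separate support. Deviations that paired arrays do not share are not covered by the cancelling. The share of Ws segments and of HSFA1 loss stays open.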
